A study of Drosophila melanogaster with 10 samples.

How the data were processed

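RNA from the midguts of adult male flies was sequenced in 10 libraries, 5 labelled control and 5 labelled dHNF4 RNAi, with a stranded TruSeq kit per the labels' protocols. Groups and replicate numbers were taken from the sample labels. The deposited table of TPM values holds 14310 genes, with totals of 975327 to 982443 per library. Per the submitters' processing notes the tools were FastQC, Trim Galore, kallisto and edgeR with the build BDGP6, with no versions. The notes do not say which tool made which table. The name of the deposited results also holds that of another tool, RUVSeq, but whether and how it was used is not stated in the labels. The authors also deposited a log2 fold change and an unadjusted p-value per gene, and these were used only as the authors' own comparison. Sequencing depth is unknown because TPM keeps none, so no counting interval was computed. TPM is a share of the library, so a fall of abundant transcripts raises the TPM of all other genes, and gene copies with near-identical sequence divide reads by estimation.

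Gene symbols came from the deposited files, and 14263 of the 14310 identifiers matched the reference annotation (release 115, assembly BDGP6.54), which gave the coordinates. TPM were analysed as log2(TPM + 1), with a pseudocount of 1, which understates the change of low genes. The 8784 genes with a mean TPM of at least 1 over the 10 libraries were tested and 5526 were not. Groups were compared with limma 3.58.1 in R 4.3.3 (linear model, moderated statistics with a mean-variance trend, two-sided), with no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Library measures were compared by an exact permutation test over all assignments of the libraries. Authors' p-values in the deposited table were counted at 0.05 without adjustment. After Benjamini-Hochberg adjustment, computed here, 3009 genes of the authors' deposited table passed, 1571 higher and 1438 lower.

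The 38 gene lists cover digestion, lipid, sugar and mitochondrial metabolism, detoxification, metals, immunity, signalling, proliferation, translation, stress, transcription, and markers of the cell types of the midgut and of adhering tissues. They were written from general knowledge, and 987 of 1092 member names given were found in the table. Lists with at least 4 tested members were tested with camera in limma, with a preset correlation between genes of 0.01 and adjustment over the lists. The alternatives were a correlation estimated per list and fry, which asks whether the genes of a list move on balance one way and makes no comparison with other genes. Fry was run on the TPM as deposited alone and called 30 lists, 15 up and 15 down.

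Named genes followed a rule. It took Hnf4 in every library, the 8 largest increases and 8 largest decreases among called genes with a mean of at least 5 TPM in the higher group and no overlap between groups, and the 6 largest differences in mean TPM. From each list described it took up to 4 called members by smallest adjusted p. The gene w was added after its values were seen.

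The groups, tests, lists, rule for named genes and alternatives were chosen before the data were examined. Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at a mean of 5 TPM, median-of-ratios scaling, rescaling without the 20 most abundant and the mitochondrially encoded genes, and quantile normalization. The others were the replicate number as a block, 1 or 2 residual factors, moderation without trend or with robust estimates, library weights, and leaving out each library in turn. The comparison was tested on simulated data with 200 changed genes among 8784. It recovered 42 of 66 genes (63.6%) changed by 0.5 on the log2 scale, 62 of 67 (92.5%) changed by 1 and 67 of 67 changed by 2, and 8 unchanged genes were called, 4.47% of the calls. The simulation held few changed genes, noise independent between genes and no shift common to all genes. These rates therefore do not describe data in which most genes changed or the scaling moved the centre.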

Results

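The series measured gene expression in the midgut of adult male Drosophila melanogaster by RNA sequencing. Flies were kept at 25 °C under 12 h of light, fed yeast alone, and dissected on day 7 after eclosion. Each library came from the pooled RNA of 20 midguts. The 10 libraries form 2 groups of 5 labelled biological replicates. Control males carried an RNAi transgene against Hnf4, the fly orthologue of the nuclear receptor HNF4, without a driver. Males of the other group carried the same transgene with mex-GAL4, which drives expression in enterocytes, the absorptive cells of the midgut. The comparison asks how expression in the whole midgut differs when the knockdown construct is expressed in enterocytes, and the driver itself is present in that group alone. Values are TPM, the share of transcripts in a library scaled to a fixed total, which keep no sequencing depth, so the depth behind each value is unknown. TPM are given as mean ± SD of 5 libraries per group, and log2 fold changes are on the log2(TPM + 1) scale with limma's adjusted p. Libraries of the same group correlated at r of at least 0.968 across genes, and libraries of different groups at no more than 0.925. The leading principal component held 77.6% of the variance and separated the groups, and control replicate 2 lay nearest to the other group, at -31.76 against -49.35 to -45.87 for the other controls.

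**Figure D1:**
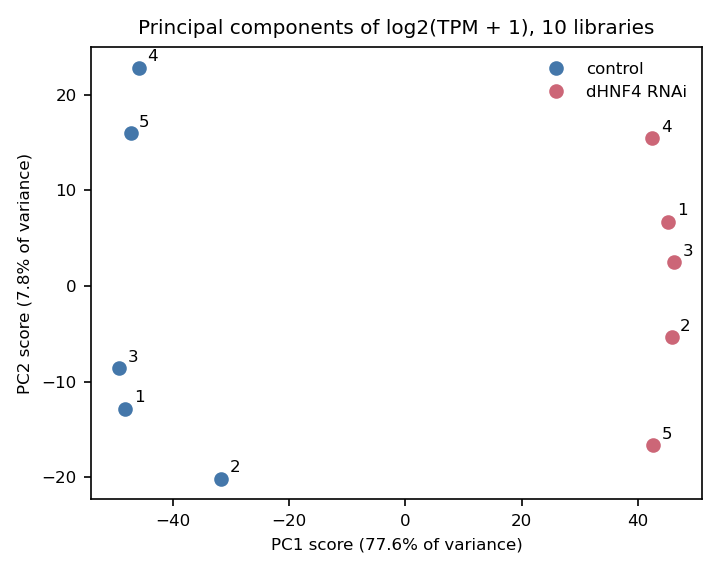
Scores of the 10 libraries on principal components 1 and 2 of log2(TPM + 1), with control libraries in blue, libraries labelled dHNF4 RNAi in red, and replicate numbers beside the points. The component on the x axis, with 77.6% of the variance, separates the groups, and control replicate 2 has the score nearest to the other group, -31.76.

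Hnf4 itself, the targeted gene (FBgn0004914, chromosome 2L, 8687226 to 8709611, minus strand, BDGP6.54), was not lower in TPM in the libraries labelled dHNF4 RNAi. It measured 36.6, 45.8, 41.8, 36.3 and 33.5 TPM in control replicates 1 to 5, with a mean of 38.8 ± 4.92. In the libraries labelled dHNF4 RNAi it measured 42.1, 46.1, 47.4, 44.7 and 48.0 TPM, with a mean of 45.6 ± 2.38. The log2 fold change was 0.24 (SE 0.083, adjusted p = 0.0199), and without control replicate 5 it was 0.19 with adjusted p = 0.0502. After median-of-ratios scaling of the TPM the sign turned, to -0.35 with adjusted p = 0.000815. In the authors' deposited table the log2 fold change of Hnf4 was -0.208 with an unadjusted p of 0.419. The TPM scale therefore shows no decrease of the target gene. All genes tested had a median log2 fold change of 0.55 on that scale, and relative to it Hnf4 was at -0.31. Its sign depends on the scaling and does not decide whether the labels are right. Every direction below is that of libraries labelled dHNF4 RNAi against libraries labelled control.

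Of 8784 genes tested, 7307 (83.2%) passed the threshold, 5878 of them higher and 1429 lower in the libraries labelled dHNF4 RNAi. The median log2 fold change of all genes tested was 0.55, a 1.46-fold shift, and values below are as measured unless said to be relative to this median or rescaled. With median-of-ratios scaling the median was 0.01 and 6274 genes passed, 3129 higher and 3145 lower, so that 49.9% of the calls were higher against 80.4% on the TPM scale. Of these, 4558 genes passed in the same direction under both scalings (3129 higher, 1429 lower) and 660 in opposite directions. Changes of at least 2-fold were seen for 1858 genes, 1447 higher and 411 lower, and under median-of-ratios scaling for 341 higher and 1012 lower. Changes of at least 8-fold were more often decreases, with 62 genes lower and 40 higher, and at 32-fold 12 were lower and 2 higher. The groups did not overlap in 6326 genes (72%), where chance gives 0.794% if no shift is common to all genes. Such a shift was present, with a median TPM of the genes tested of 12.8 ± 0.953 in the controls and 19.0 ± 0.314 in the other group. It can separate the groups by itself, and the share after rescaling was not computed.

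**Figure D2:**
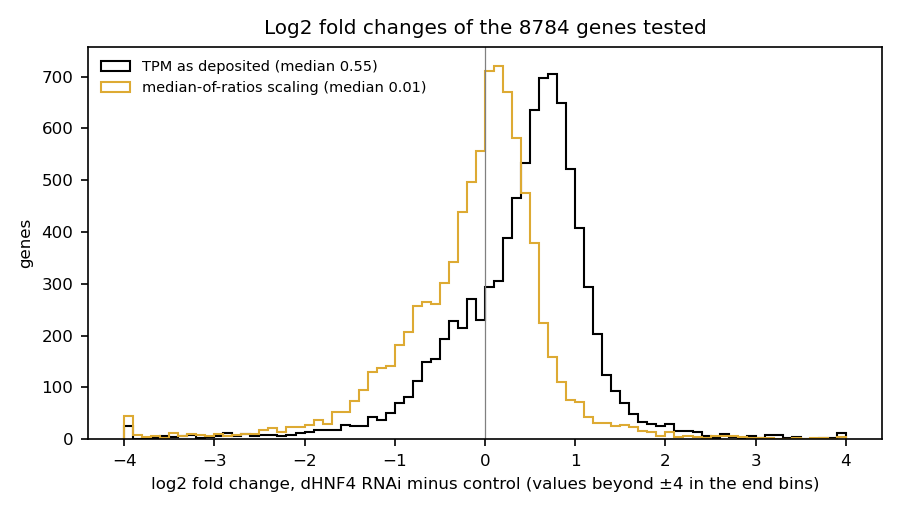
Number of genes (y axis) by log2 fold change, libraries labelled dHNF4 RNAi minus control (x axis), for the 8784 genes tested, with TPM as deposited in black and after median-of-ratios scaling in yellow. The distribution on the TPM scale is centred at 0.55 and the rescaled one at 0.01, which turns the calls from 5878 higher and 1429 lower to 3129 higher and 3145 lower.

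The largest decreases were in secreted digestive enzymes and in a receptor for lipid-soluble molecules. CG17571, a serine endopeptidase (FBgn0259998), averaged 1131 ± 191 TPM in the controls and 1.31 ± 1.36 in the libraries labelled dHNF4 RNAi, a log2 fold change of -9.11 (SE 0.33, adjusted p = 2.81e-09). CG11911, of the same class, went from 729 ± 132 to 1.57 ± 1.01 TPM (-8.22, adjusted p = 4.59e-10). The scavenger receptor ninaD, needed for carotenoid uptake, went from 346 ± 111 to 1.38 ± 0.885 TPM (-7.21, adjusted p = 7.13e-09), and the beta-galactosidase Gal from 320 ± 71.3 to 2.32 ± 0.0676 TPM (-6.56, adjusted p = 4.61e-11). The trypsin gene gammaTry fell from 2089 ± 710 to 34.2 ± 35.6 TPM, a value that is uncertain because its near-identical neighbours share reads with it. CG8299, the lipase-like CG31089 and the serine endopeptidase CG31269 fell, with log2 fold changes of -6.34, -5.81 and -5.51. Among the increases, Ret, a receptor tyrosine kinase, rose from 0.621 ± 0.147 to 128 ± 9.45 TPM (log2 fold change 6.32, SE 0.078, adjusted p = 8.78e-13). Vajk3 rose from 0.168 ± 0.154 to 42.2 ± 5.06 TPM and exp from 0.928 ± 0.173 to 45.7 ± 7.10 TPM, by 5.21 and 4.59 on the log2 scale. The acyl-CoA binding protein gene Acbp6 (4.69), the lysozyme gene LysX (4.30), CG14499 (4.25), Erasp (4.24) and the drosomycin-like Drsl3 (4.05) rose with a wide spread among controls. Control replicate 2 held 155 TPM of Acbp6 and 74.5 TPM of LysX, where the other controls held 5.20 to 27.4 and 2.08 to 14.7. All 16 of these genes kept direction and call under median-of-ratios scaling, which changes of this size made near certain. The eye colour gene w, chosen after its values were seen and mutant in both genotypes, was at 1.28 ± 0.216 TPM in the controls and at 36.0 ± 1.13 in the other group (4.02, adjusted p = 2e-11). The driver is present in that group alone, so this difference cannot be ascribed to the knockdown.

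**Figure D3:**
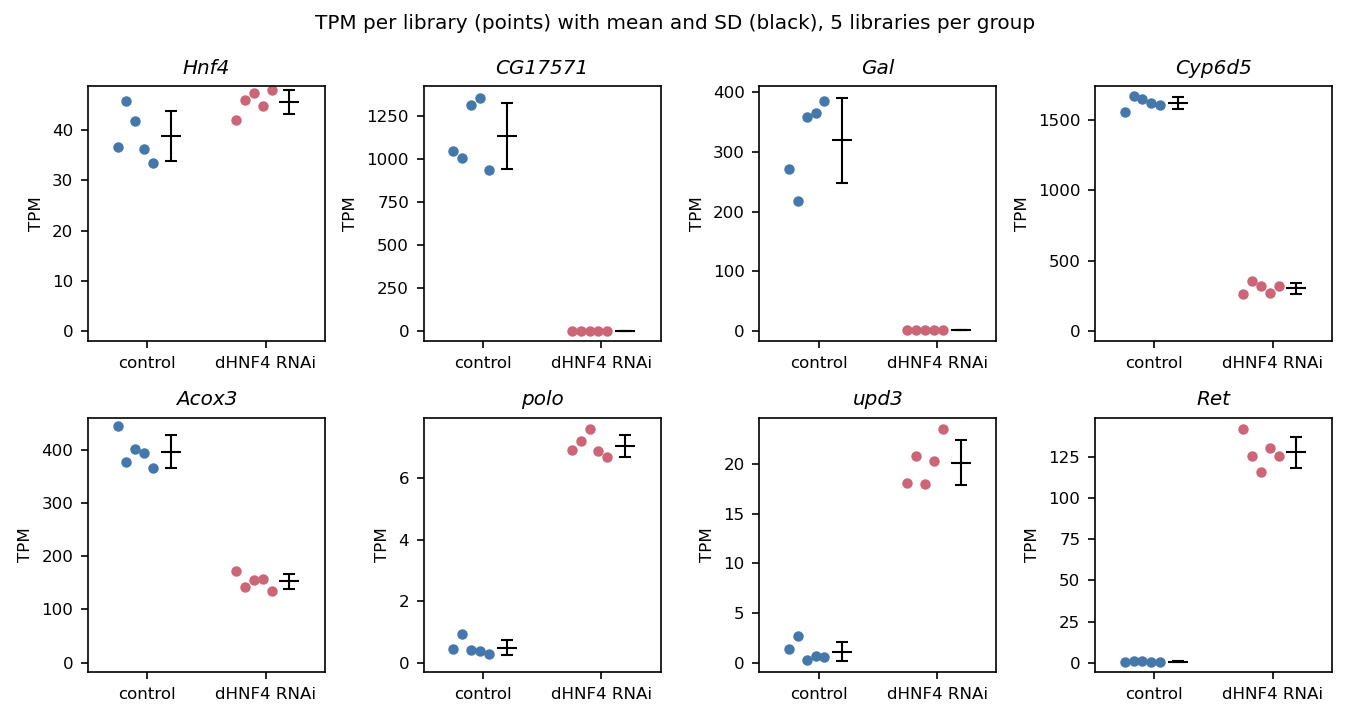
TPM (y axis) of 8 genes in each of the 5 control libraries (blue) and 5 libraries labelled dHNF4 RNAi (red), with the mean and SD of each group in black. Hnf4 averages 38.8 in the controls and 45.6 in the other group and its direction turns under median-of-ratios scaling, CG17571, Gal, Cyp6d5 and Acox3 are lower, and polo, upd3 and Ret are higher in every library labelled dHNF4 RNAi than in any control.

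Digestive enzymes were lower as groups under both scalings with camera's preset correlation. Under median-of-ratios scaling with an estimated correlation none of the 5 lists below passed (camera adjusted p from 0.156 to 0.307). Of 55 serine endopeptidases tested, 37 fell, 11 rose and 7 did not pass. Under median-of-ratios scaling 44 fell and 5 rose. The TPM of all members together were 139700 ± 31800 in the controls and 118600 ± 11400 in the other group, a difference smaller than the SD of the controls. Their median log2 fold change was -1.01, or -1.56 relative to the all-gene median (camera adjusted p = 1.01e-17, and adjusted p = 0.0588 with an estimated correlation). CG11912 fell by 5.36 and CG4053 by 3.55 on the log2 scale. Among the carbohydrate-digesting enzymes, 25 of 38 fell and 7 rose, and 30 and 6 under median-of-ratios scaling. Their median was -0.99 (camera adjusted p = 3.49e-13, and adjusted p = 0.00476 with an estimated correlation). The maltase genes Mal-A4 (1099 ± 198 to 74.99 ± 9.63 TPM), Mal-A3 (1027 ± 194 to 93.2 ± 17.0) and Mal-A8 (2632 ± 346 to 502 ± 49.5) were among them. Of 24 carboxypeptidases and aminopeptidases, 16 fell and 4 rose, and 20 and 0 under median-of-ratios scaling (median -0.59, camera adjusted p = 6.4e-10, and adjusted p = 0.0232 with an estimated correlation). CG8560 (680 ± 79.5 to 23.4 ± 4.08 TPM) and CG17633 (1498 ± 226 to 94.1 ± 14.5 TPM) fell. Of 19 lipases, 14 fell and 3 rose, and 15 and 2 under that scaling (median -0.67, camera adjusted p = 1.24e-08, and adjusted p = 0.00719 with an estimated correlation). CG2772, CG31091 and CG6277 fell, with log2 fold changes of -2.83, -5.49 and -1.56. Of 12 lysozymes, 6 fell and 1 rose, and 8 and 1 under that scaling (median -0.46, camera adjusted p = 0.000503, and adjusted p = 0.135 with an estimated correlation). LysE was at 59.9 ± 7.45 TPM in controls and 4.56 ± 2.57 in the other group. The largest differences in TPM fell in abundant genes, with Amy-p, an amylase, at 18270 ± 1384 and 8595 ± 1389, CG14645 at 24080 ± 2856 and 15130 ± 2639, Mal-A1 at 14480 ± 1425 and 6888 ± 655, yip7 at 13090 ± 2802 and 6064 ± 484, Jon99Cii at 16300 ± 6213 and 9808 ± 1084, and LysD at 9586 ± 1905 and 3566 ± 1849. The 20 most abundant genes took 24.9% ± 2.01 of the TPM in the controls and 17.8% ± 0.341 in the other group (two-sided exact permutation p = 0.00794, the smallest that the assignments of the libraries can give). The amylase, maltase, Jon, trypsin and lysozyme genes have close copies that share reads, so the division between copies is uncertain. Counts of members adjusted over the list alone were the same as those over all genes tested in these 5 lists, and in the lists below unless another count is given.

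In fatty acid and glyceride synthesis, 18 of 30 genes fell in the libraries labelled dHNF4 RNAi and 3 rose, and 26 and 0 under median-of-ratios scaling (median -0.43, or -0.98 relative to all genes, camera adjusted p = 2.36e-10, and adjusted p = 0.00719 with an estimated correlation). The diacylglycerol acyltransferase gene mdy went from 12.9 ± 1.49 to 4.10 ± 0.528 TPM, the acyltransferase gene Agpat3 from 200 ± 24.3 to 77.8 ± 1.38, the acyl-CoA synthetase gene Acsl from 237 ± 19.6 to 104 ± 11.4 and the fatty acid transport gene Fatp1 from 162 ± 9.07 to 92.6 ± 6.42. In fatty acid beta-oxidation, 18 of 31 genes fell and 8 rose, and under median-of-ratios scaling 22 fell and 1 rose. The median was -0.26 (camera adjusted p = 5.13e-07, and adjusted p = 0.187 with an estimated correlation). The acyl-CoA oxidase genes Acox3 (396 ± 30.7 to 152 ± 13.9 TPM) and Acox57D-p (137 ± 10.3 to 62.1 ± 6.68 TPM) and the dehydrogenase gene Acadvl (124 ± 8.38 to 74.6 ± 3.69 TPM) fell, and CG4860 rose by 0.73 on the log2 scale. In very-long-chain fatty acid and hydrocarbon synthesis, 8 of 15 genes fell and 2 rose, against 8 and 1 adjusted over the list alone and 10 and 0 under median-of-ratios scaling (median -0.44, camera adjusted p = 1.2e-05, and adjusted p = 0.11 with an estimated correlation). The elongation genes Hacd1 (-0.73) and bond (-0.77) fell. Lipid transport genes went both ways, with 13 of 31 lower and 10 higher, and 21 lower and 3 higher under median-of-ratios scaling (median -0.15, camera adjusted p = 1.2e-05, and adjusted p = 0.0588 with an estimated correlation). Npc2d and Npc2f, of a family of sterol-binding proteins, fell (log2 fold changes -4.84 and -4.35), while Npc2e rose from 115 ± 38.4 to 1467 ± 177 TPM. Markers of the fat body, a tissue that adheres to the gut and shares lipid genes with it, were lower as well, with 12 of 21 lower and 1 higher, and 16 and 1 under median-of-ratios scaling (median -0.67, camera adjusted p = 5.13e-07, and adjusted p = 0.131 with an estimated correlation). The marker to went from 302 ± 53.9 to 146 ± 12.9 TPM, and Tep4 was the marker that rose, from 49.7 ± 7.85 to 107 ± 8.19 TPM.

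Genes of detoxification and metal handling held steep decreases. Of 71 cytochrome P450 genes, 40 fell and 13 rose, and 53 and 7 under median-of-ratios scaling (median -0.43, or -0.98 relative to all genes, camera adjusted p = 1.34e-14, and adjusted p = 0.0147 with an estimated correlation). Cyp6d5 went from 1619 ± 43.0 to 305 ± 38.6 TPM, Cyp28a5 from 176 ± 50.5 to 7.64 ± 1.36, Cyp6a20 from 56.7 ± 6.22 to 2.61 ± 0.472 and Cyp4ac1 from 74.0 ± 8.60 to 11.7 ± 0.930. Glutathione S-transferases went both ways, with 14 of 35 lower and 13 higher, and 18 lower and 8 higher under median-of-ratios scaling. Their median was 0.15 and their mean -0.04, and camera placed them below other genes (adjusted p = 0.000503, and adjusted p = 0.205 with an estimated correlation). GstE7 and GstE9 fell by 2.67 and 2.83 on the log2 scale and GstO3 rose by 1.55. Of 27 UDP-glycosyltransferases, 11 fell and 10 rose, and 19 fell and 4 rose under median-of-ratios scaling (median -0.08, camera adjusted p = 0.000503, and adjusted p = 0.131 with an estimated correlation). Ugt37B1 fell by 4.45 and Ugt37D1 by 2.22, and Ugt316A1 rose by 1.02. Of 39 heat shock and antioxidant genes, 18 rose and 11 fell, which turned to 11 and 19 under median-of-ratios scaling (median 0.16, camera adjusted p = 0.0272 below other genes, adjusted p = 0.552 with an estimated correlation, and 0.161 under that scaling). The peroxiredoxin gene Prx6c fell from 144 ± 17.3 to 7.46 ± 1.17 TPM and Gclm, for a subunit of the enzyme that starts glutathione synthesis, from 430 ± 48.5 to 140 ± 7.42. The peroxiredoxin gene Prx4 rose from 34.8 ± 2.80 to 79.4 ± 4.13 TPM and the chaperone gene Hsp60A from 104 ± 8.24 to 232 ± 13.5. All 4 kept direction and call under that scaling. In the metallothionein, ferritin and metal transport list 11 of 28 rose and 8 fell, which turned to 1 and 18 under median-of-ratios scaling (median -0.12, camera adjusted p = 0.00251, and adjusted p = 0.205 with an estimated correlation). MtnC, a metallothionein, fell from 2706 ± 458 to 468 ± 109 TPM, and the copper transporter gene Ctr1B rose from 64.5 ± 9.95 to 320 ± 162 TPM. Among markers of copper and iron cells and acid secretion, 8 of 15 fell and 4 rose, and 12 and 0 under median-of-ratios scaling (median -0.21, camera adjusted p = 3.59e-05, and adjusted p = 0.0182 with an estimated correlation). The carbonic anhydrase gene CAH7 fell by 3.17 on the log2 scale, and Zip42C.1 was at 5.55 ± 0.621 TPM in the controls and 0.0468 ± 0.0339 in the other group.

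Genes of the cell cycle and of midgut progenitors were higher in the libraries labelled dHNF4 RNAi. Of 51 cell cycle and DNA replication genes, 50 rose and none fell, 43 of them by at least 2-fold, and 47 rose and 1 fell under median-of-ratios scaling. The median was 1.58, or 1.03 relative to all genes (camera adjusted p = 1.81e-06, and adjusted p = 0.496 with an estimated correlation). The mitotic kinase gene polo went from 0.486 ± 0.249 to 7.06 ± 0.359 TPM, and the replication genes Mcm2 from 0.750 ± 0.283 to 7.08 ± 0.685, dup from 1.93 ± 0.227 to 7.75 ± 0.382 and PolA1 from 0.308 ± 0.0897 to 3.76 ± 0.442. Of 24 markers of intestinal stem cells and enteroblasts, 22 rose and 1 fell, and 17 rose and 2 fell under median-of-ratios scaling (median 1.21, camera adjusted p = 0.0159, and adjusted p = 0.698 with an estimated correlation). Sox100B rose from 4.26 ± 2.43 to 46.1 ± 2.05 TPM, E(spl)m3-HLH, a Notch target, from 2.71 ± 1.71 to 25.7 ± 0.949 and the integrin gene mew from 16.9 ± 2.33 to 50.2 ± 2.97. In the list of JAK-STAT, EGFR and JNK pathway ligands and targets, 22 of 33 rose and 3 fell, and 15 and 9 under median-of-ratios scaling, with no call against other genes (median 0.61, camera adjusted p = 0.738). The cytokine gene upd3 rose from 1.10 ± 0.975 to 20.1 ± 2.27 TPM, the JNK phosphatase gene puc from 33.5 ± 2.74 to 116 ± 10.7, and spi and pnt, of EGFR signalling, by 1.10 and 1.26 on the log2 scale. Ribosome biogenesis genes rose in 38 of 40 cases with none lower, and 21 rose and 5 fell under median-of-ratios scaling (median 0.78, camera adjusted p = 0.00558, and adjusted p = 0.698 with an estimated correlation). Of its members eIF6 rose from 34.1 ± 4.74 to 79.4 ± 4.66 TPM. Rrp1, which the list took in by its symbol but which is a DNA repair gene in the fly, rose by 1.94 on the log2 scale. Of 30 transcription factors of midgut regions and enterocytes, 20 rose and 3 fell, which turned to 10 and 12 under median-of-ratios scaling (median 0.47, camera adjusted p = 0.833). Of these, nub rose from 54.5 ± 6.51 to 126 ± 10.6 TPM and da by 1.00 on the log2 scale. Among controls, control replicate 2 was above the others by a median of 0.40 in the cell cycle list and 0.46 in the progenitor list, against 0.18 over all genes. In the serine endopeptidase list its median difference from the other controls was -0.216. Without that library 7339 genes passed, 5992 higher and 1347 lower, and 2083 changed at least 2-fold.

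For mitochondrial and ribosomal protein genes the numbers called higher and lower depended on the scaling. Of 67 nuclear-encoded oxidative phosphorylation genes, 62 rose and 2 fell (63 and 2 adjusted over the list alone), and under median-of-ratios scaling 5 rose and 16 fell. Their median, 0.54, was that of all genes (camera adjusted p = 0.00527 above other genes, adjusted p = 0.719 with an estimated correlation, and 0.314 below other genes under median-of-ratios scaling). ATPsyngamma rose from 296 ± 8.47 to 510 ± 18.5 TPM and SdhB from 132 ± 3.72 to 228 ± 13.4. Of 84 ribosomal protein genes, 77 rose and 2 fell (78 and 2 adjusted over the list alone), whereas 1 rose and 69 fell under median-of-ratios scaling (median 0.31, camera adjusted p = 0.068), where camera placed the list below other genes (adjusted p = 1.83e-07, and adjusted p = 0.55 with an estimated correlation). RpS7 rose by 0.52 on the TPM scale and had -0.08 after median-of-ratios scaling, while RpS29 fell under both, by 1.04 and 1.64. In the tricarboxylic acid cycle, 14 of 22 genes rose and 4 fell, which turned to 1 and 11 under median-of-ratios scaling (median 0.43, camera adjusted p = 0.681), where camera placed the list below other genes (adjusted p = 0.0442, and adjusted p = 0.626 with an estimated correlation). Idh, the only member of the list called at least 2-fold lower on the TPM scale, fell from 1529 ± 338 to 483 ± 74.0 TPM. Of 13 mitochondrially encoded proteins, 5 rose and 2 fell, and 0 and 6 under median-of-ratios scaling (median 0.20, camera adjusted p = 0.253), with mt:CoII at 1898 ± 250 and 2720 ± 180 TPM. The mitochondrially encoded genes together took 0.898% ± 0.124 of the TPM in the controls and 1.29% ± 0.154 in the other group (two-sided exact permutation p = 0.00794).

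The enterocyte, enteroendocrine and visceral muscle marker lists had lower medians than the progenitor list under both scalings. Of 22 enterocyte brush border and septate junction markers, 10 rose and 6 fell, which turned to 6 and 10 under median-of-ratios scaling (median 0.01, camera adjusted p = 0.0362 below other genes, adjusted p = 0.424 with an estimated correlation, and 0.227 under that scaling). The enterocyte gene mex1, whose regulatory sequence gives the driver its name, rose from 490 ± 26.4 to 894 ± 47.6 TPM, while the alkaline phosphatase genes Alp9 and Alp10 fell by 2.54 and 2.79 on the log2 scale. Of 29 enteroendocrine markers, 13 rose and 7 fell (13 and 4 adjusted over the list alone), which turned to 3 and 17 under median-of-ratios scaling (median 0.20, camera adjusted p = 0.099), where camera placed the list below other genes (adjusted p = 0.0245, and adjusted p = 0.46 with an estimated correlation). The peptide hormone gene CCHa1 rose by 1.00, and Phm rose by 0.44 but had -0.15 after median-of-ratios scaling. Of 32 visceral muscle markers, 7 rose and 7 fell (7 and 6 adjusted over the list alone), and 2 and 26 under median-of-ratios scaling (median -0.09, camera adjusted p = 0.000979, and adjusted p = 0.535 with an estimated correlation). On the TPM scale flr rose by 0.93 and Tm1 by 0.61, and Tm1 was at 0.01 after median-of-ratios scaling. Of 10 tracheal markers 5 fell and 1 rose, and 9 and 0 under median-of-ratios scaling (median -0.33, camera adjusted p = 0.000892, and adjusted p = 0.131 with an estimated correlation). Of 21 Malpighian tubule markers 6 fell and 3 rose, and 9 and 1 under that scaling (median -0.08, camera adjusted p = 0.000566, and adjusted p = 0.205 with an estimated correlation). Among 11 hemocyte markers 4 rose and 3 fell, and 1 and 6 under median-of-ratios scaling (median -0.13, camera adjusted p = 0.0605). Among testis and accessory gland markers 7 of 58 were expressed enough to test, of which 3 rose and 1 fell, or 2 and 2 under median-of-ratios scaling (median 1.303, camera adjusted p = 0.663).

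**Figure D4:**
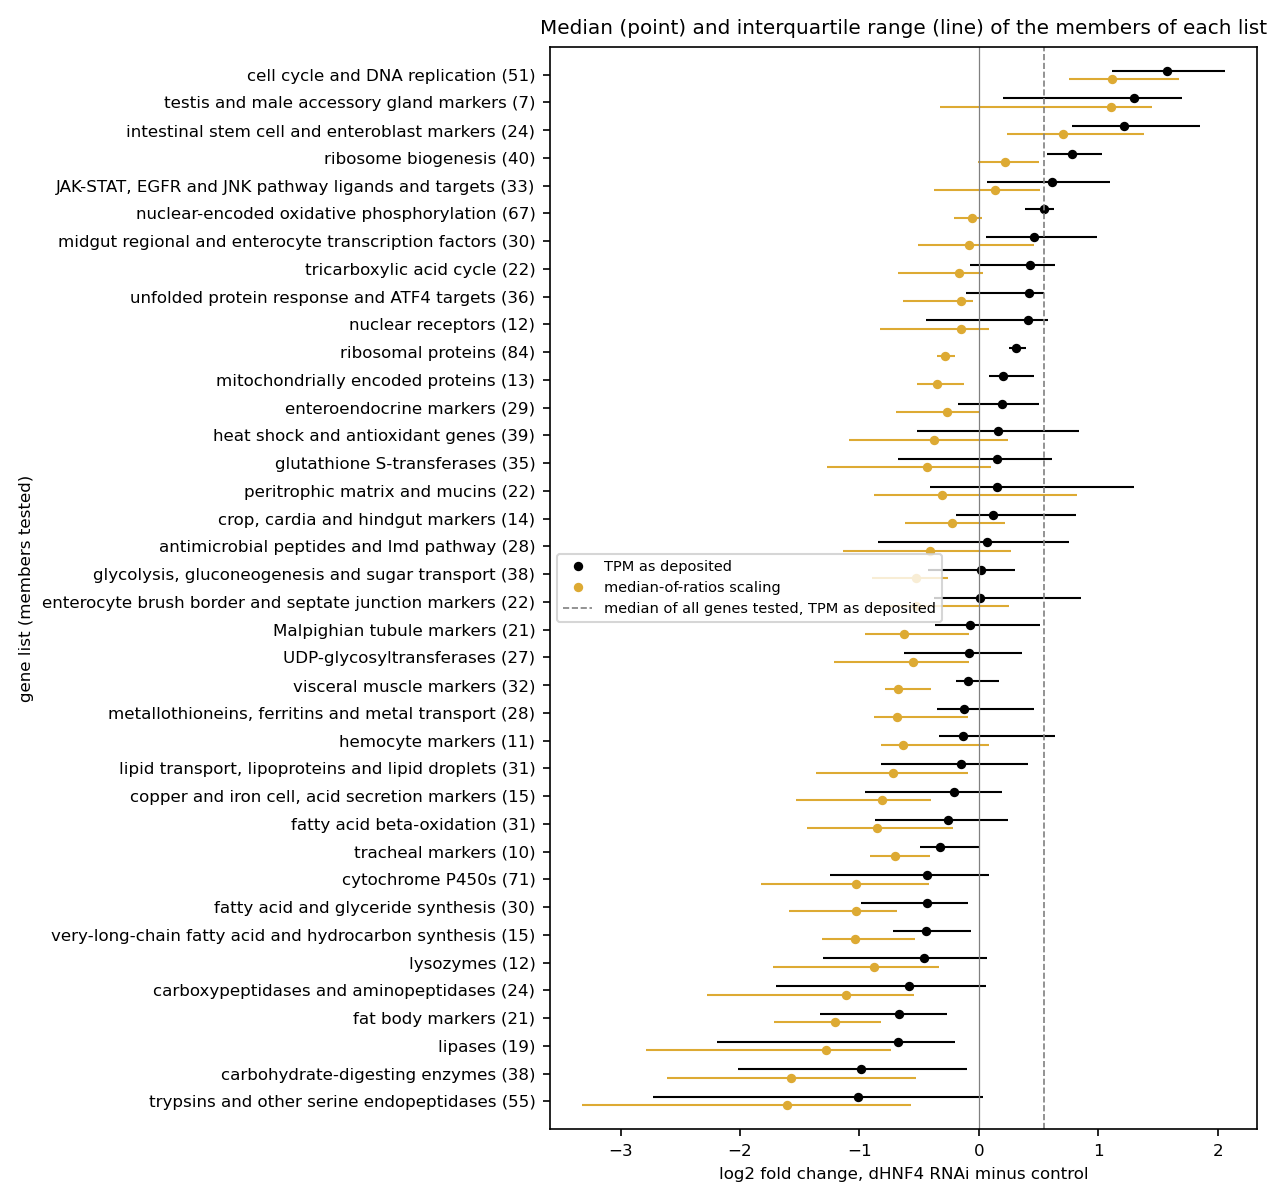
Median (point) and interquartile range (line) of the log2 fold change, libraries labelled dHNF4 RNAi minus control (x axis), over the tested members of each of 38 gene lists (y axis, number of members in brackets), with TPM as deposited in black and after median-of-ratios scaling in yellow. The cell cycle list has medians of 1.58 and 1.11 and the serine endopeptidases of -1.01 and -1.61, while lists such as the ribosomal proteins (0.31 and -0.29) and oxidative phosphorylation (0.54 and -0.06) change sign with the scaling.

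Of the 38 lists, 26 passed with camera's preset correlation, 4 higher and 22 lower than other genes, and 6 passed with an estimated correlation. These 6, all lower, were fatty acid and glyceride synthesis, lipases, carboxypeptidases and aminopeptidases, carbohydrate-digesting enzymes, cytochrome P450s and copper and iron cell markers. Under median-of-ratios scaling 1 list passed with an estimated correlation, the cytochrome P450s (adjusted p = 0.00543). The median, the mean and the test of a list differed in sign in 15 lists. The authors' deposited table holds 10494 genes, of which 4177 had an unadjusted p under 0.05, 2301 higher and 1876 lower. Among the 8769 genes tested in both, the log2 fold changes of the authors' deposited table correlated with those from the TPM at r = 0.92 (rho = 0.931) across genes, which are not independent replicates, and both come from the same libraries. The median difference of the authors' deposited table from the TPM values was -0.40. Of 3621 such genes with p under 0.05 in the authors' deposited table, 3301 were called in the same direction on the TPM scale and 1 in the opposite direction, and 3500 and 0 after median-of-ratios scaling. For Ret the authors' deposited table gave a log2 fold change of 7.07, for CG17571 -8.61, and for polo 3.33. For Acbp6, LysX and CG14499 the authors' deposited table gave 1.80, 2.00 and 1.99, below the values from the TPM, with unadjusted p of 0.0926, 0.0547 and 0.0535.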

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

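The tests of exchanged libraries, hairpin reads, the 20 most abundant genes and both tests of the cell cycle genes were chosen after the result was seen, as were the comparisons of control replicate 2 with the other controls. The tests of the 500 most abundant genes and of other splits were set beforehand.

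In 23 of 236 group values, 1 library lay far from the other 4 of its group, where chance gives about 1 in 20, or 11.8. Control replicate 2 held 11 of the 23. There, TPM was low for Agpat3 (158, others 205 to 221), Npc2f (381, others 480 to 504) and MtnC (1930, others 2710 to 3050). It was high there for Ctr1B (81.9, others 57.9 to 63.2), polo (0.923, others 0.295 to 0.429), Mcm2 (1.25, others 0.551 to 0.704), nub (65.8, others 49.1 to 53.2), Phm (79.0, others 69.9 to 72.4), PGRP-LA (34.8, others 25 to 27.2) and usp (20.5, others 15.7 to 16.9). The score of that library on the leading principal component was -31.76, others -49.35 to -45.87. Control replicate 2 was the highest control in 73.9% of the genes at least 2-fold higher in the libraries labelled dHNF4 RNAi (57.1% of all genes tested) and the lowest in 30.2% of those at least 2-fold lower (7.97% of all genes tested). After median-of-ratios scaling these shares were 47.8% (26.7% of all genes) and 53.8% (28.9% of all genes). In the TPM as deposited, Ret was at 0.786 in control replicate 2, against 0.415 to 0.728 in the other controls.

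In the other controls, yip7 was at 18000 TPM in control replicate 1 (others 10900 to 12600) and LysE at 46.9 in the same library (others 61 to 65.8). In control replicate 3, CG6277 was at 618 TPM (others 730 to 778) and CG4860 at 9.62 (others 8.01 to 8.35). Among libraries labelled dHNF4 RNAi, replicate 1 held 30.7 TPM of CG8560 (others 21.4 to 21.8) and 917 of Muc68D (others 1170 to 1270), and replicate 2 held 589 of Mal-A8 (others 465 to 491). Replicate 3 held 104 TPM of Fatp1 (others 87.8 to 92) and 8.92 of Npc2d (others 13.6 to 14.4). Replicate 4 held 10 TPM of Cyp28a5 (others 6.59 to 7.39), and replicate 5 held 42.6 of Sox100B (others 46.1 to 47.5) and 121 of Tep4 (others 102 to 107).

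Of 100 splits of the 10 libraries into 5 and 5, 1 gave as many genes changed as the 7307 counted, the real one. The highest of the others gave 28. Every other split mixed the groups and put their difference into the spread within each side, so low counts there were fixed in advance. The splits therefore give no rate of false calls and cannot address a difference that coincides with the groups. The median log2 fold change of all genes lay above 0 on the TPM scale. Rescaling without the 20 most abundant and the mitochondrially encoded genes left it at 0.437, which argues against these genes as its whole cause. The 500 most abundant genes took 75.6% ± 1.42 of the TPM in the controls and 69.6% ± 0.312 in the other group (SD, n = 5), and without them the median of the other genes went from 0.57 to 0.281. That lies between the bounds set beforehand, under 0.1 if these genes were the cause and above 0.3 if not. By those bounds the test did not decide. The SE of the 0.281 over libraries, computed after that value was seen, was 0.012. A remainder that far above 0 argues against the share of these genes as the whole cause. The fall from 0.57 leaves it open as a part. TPM are shares of a fixed total, so a difference in total RNA per gut would not by itself move this median.

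Hnf4 was not lower in TPM in the libraries labelled dHNF4 RNAi. The lowest correlation within groups exceeded the highest between groups by 0.043, which argues against single libraries exchanged between the groups. Reads of the hairpin counted as Hnf4 could hide a decrease, and the gene-level log2 fold change of 0.237 sums all transcripts, so this cannot be told apart from an unchanged messenger. The scaling also decides the sign, with -0.35 after median-of-ratios scaling, and a weak knockdown in the whole tissue stays open, as untested.

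Cell cycle and progenitor genes were higher in the libraries labelled dHNF4 RNAi. Under median-of-ratios scaling the median of the cell cycle list was 1.113. That followed from its 1.03 relative to all genes on the TPM scale, so it is no separate test. Both values show that a shift common to all genes does not account for the whole rise of this list. With an estimated correlation camera did not call the list under that scaling (adjusted p = 0.224). A lower share of enterocytes alone would raise all other cell types alike, but the progenitor median exceeded the higher of the enteroendocrine and muscle medians by at least 0.866 in each library labelled dHNF4 RNAi. Of the progenitor markers, 2 are shared with these lists, and polo is also in the cell cycle list. What stays open, as a hypothesis, is that progenitors may be more numerous or divide more, with or without a lower share of enterocytes beside it. The presence of the driver in that group alone is confounded with the knockdown.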

How the results depend on the processing

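All alternatives were set beforehand. The 111 named genes besides Hnf4 were taken from these same libraries, nearly all for a small adjusted p or a large change. That they would keep their calls was therefore largely fixed by the choice. All of them kept direction and call in each of the 1110 comparisons without 1 library. They also did so under every other setting in which they were tested except median-of-ratios scaling (107 kept, 3 lost their call and Phm, with adjusted p = 0.0204, was called the other way) and quantile normalization (109 kept, 2 lost their call). The values that changed sign under median-of-ratios scaling were -0.15 for Phm and, with the call lost, -0.077 for RpS7 and -0.074 for mt:CoII. Camera's direction for the oxidative phosphorylation list turned from higher to lower than other genes with the call lost, while its median relative to all genes was -0.005 on the TPM scale and -0.066 after that scaling. Hnf4 had -0.35 under median-of-ratios scaling and -0.18 under quantile normalization, and after rescaling without the 20 most abundant and mitochondrially encoded genes it had 0.11 and lost its call (adjusted p = 0.202). Leaving out 1 library gave 0.19 (without control replicate 5, adjusted p = 0.0502) to 0.30, over adjusted p of 0.00208 to 0.0502. Genes higher and lower numbered 3129 and 3145 under median-of-ratios scaling and 3888 and 2557 under quantile normalization. The scalings set the centre of the fold changes, and beyond that the cause was not tested. Genes changed at least 2-fold numbered 950 with a pseudocount of 5, which shrinks the change of low genes, and 1225 under quantile normalization. With an estimated correlation 6 lists passed in place of 26, and under median-of-ratios scaling 26 passed as well: 22 of the 26 kept their call and direction, 4 lost it (oxidative phosphorylation, peritrophic matrix and mucins, heat shock and antioxidant genes, enterocyte markers) and 4 others gained one, as lower (ribosomal proteins, tricarboxylic acid cycle, unfolded protein response, enteroendocrine markers). Fry, which makes no comparison with other genes and was run on the TPM as deposited alone, called 30 lists, 15 up and 15 down. Of camera's 26 it called 19 in the same direction and 1, the heat shock and antioxidant genes, in the opposite one, and 6 not at all. Another 10 were called by fry alone. Its up calls carry the shift common to all genes. The ribosomal proteins were called up (fry adjusted p = 0.00011) but had a median of -0.29 after median-of-ratios scaling. Without 1 library, genes changed ranged from 7164 to 7339, those at least 2-fold from 1770 to 2083, higher from 5790 to 5992, lower from 1347 to 1456 and lists from 25 to 27.

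The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.331 to 0.358, and 2 of 10 libraries correlated best with their own number. With the replicate number as a block 7249 genes changed, 5849 higher and 1400 lower, 1858 by at least 2-fold, with Hnf4 at 0.24 (adjusted p = 0.0263) and 26 lists. Depth is unknown, so its effect on low genes could not be assessed.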

Other observations

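The tests of chromosome 2, of the spread of the serine endopeptidases and of clustering along the chromosomes were set before their results were seen, and the runs of neighbouring genes named below were chosen after.

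Sugar handling genes went both ways in the libraries labelled dHNF4 RNAi. Of 38 genes of glycolysis, gluconeogenesis and sugar transport, 8 rose and 9 fell, and 2 and 27 under median-of-ratios scaling (median 0.02, camera adjusted p = 0.000341 below other genes, and adjusted p = 0.179 with an estimated correlation). The sugar transporter genes CG1208 (349 ± 34.3 to 69.2 ± 8.20 TPM) and CG4607 (475 ± 90.2 to 137 ± 24.3 TPM) fell, while Gapdh1 (373 ± 25.0 to 668 ± 47.3 TPM) and Pepck2 (5.37 ± 0.932 to 14.6 ± 1.46 TPM) rose (mean ± SD, n = 5). Among 22 genes of the peritrophic matrix and mucins 6 rose and 8 fell (5 and 8 adjusted over the list alone), and 4 and 11 under median-of-ratios scaling (median 0.15, camera adjusted p = 0.0159 below other genes, adjusted p = 0.384 with an estimated correlation, and 0.292 under that scaling). Mur29B rose from 223 ± 96.3 to 1667 ± 97.7 TPM and Muc68D fell from 1957 ± 259 to 1151 ± 136. In the list of crop, cardia and hindgut markers, 6 of 14 rose and 3 fell, which turned to 4 and 6 under median-of-ratios scaling (median 0.12, camera adjusted p = 0.434), and Pebp1 rose from 883 ± 125 to 2301 ± 289 TPM.

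Of 28 genes of antimicrobial peptides and the Imd immune pathway 11 rose and 3 fell (11 and 1 adjusted over the list alone), which turned to 6 and 9 under median-of-ratios scaling (median 0.07, camera adjusted p = 0.101). In the libraries labelled dHNF4 RNAi, pirk rose from 16.6 ± 3.38 to 59.5 ± 12.7 TPM, PGRP-LB from 125 ± 10.9 to 244 ± 33.1, PGRP-LA from 27.9 ± 3.98 to 54.9 ± 3.79 and key from 48.9 ± 7.68 to 99.2 ± 4.81. Among 12 nuclear receptors 7 rose and 4 fell, which turned to 2 and 6 under median-of-ratios scaling (median 0.42, camera adjusted p = 0.271), and the partners usp and EcR of the ecdysone receptor rose by 1.01 and 0.80 on the log2 scale, and by 0.43 and 0.29 under that scaling. Of 36 genes of the unfolded protein response and ATF4 targets, 21 rose and 6 fell, which turned to 3 and 16 under median-of-ratios scaling (median 0.42, camera adjusted p = 0.362), where camera placed the list below other genes (adjusted p = 0.0177, and adjusted p = 0.319 with an estimated correlation). ERp60 and scyl rose by 1.03 and 1.71 on the log2 scale and CG7966 fell from 59.7 ± 8.24 to 10.3 ± 0.885 TPM.

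Genes at least 2-fold lower lay beside each other along the chromosomes more often than in random orders, with 84 neighbouring pairs among 410 genes, where 10000 random orders gave a median of 19 and at most 38. The longest run, of 9 genes from CG17477 to CG5255 with the serine endopeptidases CG31269 and CG4053 among them, lies on chromosome 3R from 17126088 to 17138865 (BDGP6.54), and another runs from LManIII to LManVI on 2L from 8765273 to 8781252. Tandem copies that share regulation are a candidate explanation, and reads shared between copies are another that was not tested. The log2 fold changes of the serine endopeptidases had an SD of 2.45, larger than in 100% of 10000 random lists of like expression (median 0.92). Of the members, 28 were called at least 2-fold lower and 7 at least 2-fold higher. Whether members are under different control was not tested. Genes higher by at least 2 on the log2 scale were on chromosome 2, which carries the driver, in 61 of 141 cases (43.3% against 38.7% of other genes). The odds ratio was 1.207 (95% interval 0.848 to 1.71, Fisher's exact p = 0.296). The interval excludes the ratio above 2 that was set beforehand for a background difference on that chromosome, but not a smaller one. Only strongly higher genes were counted, so a background difference that acts on few genes or lowers them could not be excluded.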
